A study of Mus musculus with 12 samples.

How the data were processed

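RNA was taken from tongue with poly-A selection, and the series design text states Illumina HiSeq2000 sequencing, comparison with the mm9 mouse genome and levels computed with Cufflinks. The submitters' processing notes also name GSNAP 2011.11.17 and edgeR, without a role for either, and what each did is not given in the sources used here. The deposited levels are 1 per gene and group, for 23235 gene rows in 6 tables, 1 for each pair of 4 numbered groups. They were read as the FPKM levels that the series design text credits to Cufflinks. The deposited p-value and q-value of each row are the authors' own and were taken as deposited. The score deposited beside them is the authors' test statistic per gene and pair, per the file headers. In 100% of tested values the p-value equalled the 2-sided normal p of that statistic to within 0.001, and the q-value equalled a Benjamini-Hochberg adjustment over the 92458 tests of all 6 tables, with a largest difference of 3.40e-06.

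The tables and labels used here do not link the group numbers to the treatments. No link was inferred from the order of the numbers or from the values, so no treatment is named for any comparison. The tables hold no values per sample, and the read depth per sample is unknown.

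The tests, thresholds, gene lists and alternatives were chosen before the data were examined, except those named as chosen after. A gene passed the test when the authors marked it as tested, the authors' deposited q was under 0.05 and 1 or both groups reached 1 FPKM. No test per gene was added for a pair of groups, because the tables used here hold only group values. Log2 differences were computed as log2(FPKM + 1) of the first group minus that of the second. Each SE came from the deposited log2 ratio divided by the authors' statistic, moved to the log2(FPKM + 1) scale by the delta method; no SE is given where that ratio or the split of variances could not be had. The 6 squared errors of a gene were resolved into 4 group variances for 14600 genes, with a largest relative misfit of 0.00184. Contrasts of 2 groups with the other 2 were tested per gene as a normal deviate with these variances, 2-sided, Benjamini-Hochberg adjusted within the contrast.

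There were 43 gene lists, 25 of pathways and 18 of cell types, with 756 genes of which 737 were found by symbol. Per list and comparison the members past the test were counted over all genes and with the authors' p adjusted over the list alone. Fisher's exact test, 2-sided, compared the share of members that were higher, or lower, with that of all other genes tested at 1 FPKM. The 510 tests were adjusted together by Benjamini-Hochberg over all comparisons, and 50 gave an adjusted p under 0.05. Fisher's test treats genes as independent, and no direction per sample can be given because there are no values per sample. List medians were also set against 10000 random lists of the same size matched on mean expression in 20 bins. Correlations of differences used the 12036 genes whose SE was at most 1 in every group, and expected values came from 20 simulated draws of unchanged groups.

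Named genes follow a rule. In each comparison these are the 8 genes with the largest rise and the 8 with the largest fall among those past the test with 1 symbol, and the 2 members of each list with the largest change, at most 30 in all, with further members of a list by largest absolute change as examples. Genes outside it were named after their values were seen: members of counts of 5 or fewer, genes of the contrasts and of the added lists, genes over the read limit, and Krt5. Some genes that the rule names are not reported here. Left out of the named genes and of the contrasts were 25 rows whose symbol had become a date and 90 rows with several symbols. These rows stayed in the counts of genes per comparison and among the other genes of Fisher's test. A further 23 genes, 10 of them keratins, exceeded the authors' read limit in 1 or more comparisons and are listed at 0 there, which is not a real 0.

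Alternatives were a q threshold of 0.01, a fold change of at least 2, no FPKM filter or 5 FPKM, adjustment within a comparison over the genes past the filter alone, Bonferroni, pseudocounts of 0 and 0.1, centring on the median, and unmatched random lists. Chosen after seeing the data were a single variance per gene for all groups, a retest after centring, leaving out salivary, seminal vesicle and precursor genes, the use of all 3 contrasts, and 7 added marker lists of granulocyte precursors, mature neutrophils, erythroid precursors, B-lineage marrow, bone cells, seminal vesicle and exocrine pancreas. Folds of these lists were taken on FPKM + 0.01, and their medians on log2(FPKM + 1) as well. Known changes were put into simulated values of 13074 genes, 200 of them changed. The variances implied by the authors' statistics were taken as the real spread. In group 4 against group 1, 24% of log2 changes of 1, 82% of 2, 92% of 3 and 100% of 4 were recovered with 3 false calls, and in group 4 against group 3 the shares were 4%, 42%, 70% and 94%. In the contrast of groups 1 and 4 with groups 2 and 3 the shares were 2%, 32%, 66% and 88%, with 4 false calls. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.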

Results

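Transcript levels were measured by RNA sequencing of tongue from 31-week-old C57BL/6 mice. The 12 samples fall into 4 treatment groups of 3. The groups received the carrier that the labels write as V.C., V.C. with ethanol, 4-NQO, or 4-NQO with ethanol; 4-NQO (4-nitroquinoline oxide) is a carcinogen that forms DNA adducts and is used to induce tumours of the mouse oral cavity. Poly-A RNA libraries were sequenced on an Illumina HiSeq2000 and set against the mm9 mouse genome. The tables used here hold 1 FPKM value per gene and group (fragments per kilobase of transcript, scaled to the number of reads) and the authors' own test for each of the 6 pairs of groups. They number the groups 1 to 4, and the sources used here do not say which number is which treatment, so every comparison below is between numbered groups. The values per sample and the read depth per sample were not used here, so the depth is unknown.

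Each of the 4 groups had between 12579 and 12741 genes at 1 FPKM or more. The authors' statistics imply a typical standard error of a gene's log2 level of 0.138 in group 1, 0.204 in group 2, 0.492 in group 3 and 0.331 in group 4, so a change of a given size was harder to detect against group 3 than against group 1. Below, a gene is said to be higher or lower when the authors' deposited q was under 0.05 and 1 or both groups reached 1 FPKM. FPKM values are the authors' value for a whole group. Differences are on the scale log2(FPKM + 1), with a standard error (SE) taken from the authors' statistic, n = 3 per group as the series states it.

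**Figure D1:**
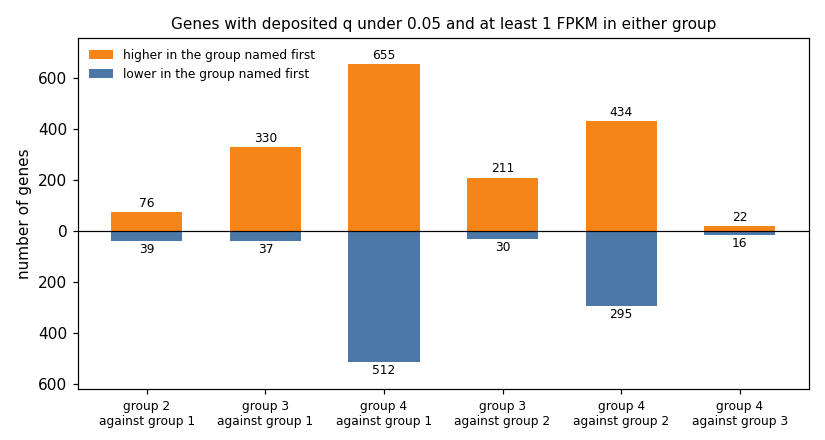
Bars give the number of genes (vertical axis) that were higher or lower in the first group than in the second for each of the 6 pairs of groups (horizontal axis). Group 4 against group 1 had the most, 655 higher and 512 lower, and group 4 against group 3 the fewest, 22 higher and 16 lower.

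Group 2 against group 1. Interferon-stimulated genes were higher in group 2. Isg15, which encodes a ubiquitin-like modifier induced by interferon (mm9 chromosome 4, 155573533 to 155574927), stood at 6.502 FPKM in group 1 and 49.99 in group 2, a log2 difference of 2.76 ± 0.28 (SE). Oas1a, which makes the activator of RNase L, went from 1.62 to 7.96 FPKM (1.77 ± 0.25), and the apolipoprotein L genes Apol9b and Apol9a rose by 2.31 ± 0.27 and 2.19 ± 0.28. The authors' deposited table gave q = 8.53e-10 for Oas1a and q = 5.69e-08 for Apol9b. Secretory genes of the salivary glands were lower: Dcpp2 fell from 423 to 121 FPKM (-1.80 ± 0.23) and Dcpp3 from 712 to 267 (-1.41 ± 0.23).

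Of the 23 measured members of the interferon list, 16 rose, 0 fell and 7 did not pass (16 higher when adjusted over the list alone), with a median log2 difference of 0.89; the share that rose exceeded that of the other genes (adjusted p = 5.35e-29, Fisher's exact test, 2-sided). Antigen presentation had 3 of 13 higher (3 adjusted over the list alone, adjusted p = 0.001004, Fisher's exact test), among them B2m, the light chain of MHC class I, at 240.1 and 482 FPKM (1.00 ± 0.25), and the immunoproteasome subunit Psmb9 (1.15 ± 0.29). Immediate early genes had 4 of 17 higher (5 adjusted over the list alone, adjusted p = 5.71e-05, Fisher's exact test), with the transcription factor Fos at 5.92 and 14.7 FPKM (1.18 ± 0.22) and the matricellular factor Ctgf at 39.0 and 81.0 (1.04 ± 0.20). The circadian list had 2 of 15 higher, Nfil3 and Per1 (2 adjusted over the list alone, adjusted p = 0.0354, Fisher's exact test), and this call ended at a q threshold of 0.01, where its adjusted p was 1 by Fisher's exact test. In the salivary gland list 5 of 12 were lower and 0 higher (6 lower adjusted over the list alone, median -0.74, adjusted p = 6.67e-09, Fisher's exact test), while the salivary amylase Amy1 and the mucin Muc5b exceeded the authors' read limit in group 1 and were not tested.

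In all, 76 genes were higher and 39 lower in group 2 among 12799 tested, and 435 had an unadjusted p under 0.05. That share is below 0.05, which unchanged genes alone would give on average if p-values held their level. The authors' p-values, and the SEs taken from them, may therefore be too large. The largest falls were the pancreatic-type amylases Amy2b (139 to 1.10 FPKM) and Amy2a5 (28.1 to 0.206), close relatives of Amy1, which was over the authors' read limit in group 1 (reads shared between these genes were not tested), and the antimicrobial lectin Reg3g (12.02 to 0.0986). The stress-response gene Nupr1 fell from 1264 to 376 FPKM (-1.75 ± 0.29). Svs4 and Svs5, which encode seminal vesicle secretory proteins, fell by 2.04 ± 0.33 and 2.26 ± 0.31 from levels of 4.46 and 6.04 FPKM. The cytochrome P450 Cyp2a5 fell from 33.6 to 16.3 FPKM. The antioxidant list had 2 of 36 lower, heme oxygenase Hmox1 (27.0 to 15.0 FPKM) and Slc7a11 (1.93 to 1.03), and 0 higher (2 lower adjusted over the list alone, adjusted p = 0.0534, Fisher's exact test). The DNA repair list (18 measured) and the p53 target list (19 measured) had 0 genes past the test. With 1 variance per gene shared by all 4 groups, chosen after seeing the data, 19 genes passed in place of 115.

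Group 3 against group 1. The largest rises were in genes of the cornifying epithelium and in alarmins. Sprr2d, a small proline-rich protein of the cornified envelope (chromosome 3, 92143062 to 92144795), stood at 0.977 FPKM in group 1 and 815 in group 3, a log2 difference of 8.69 ± 0.58; the Sprr2 genes are close paralogs, and how far reads were shared between them was not tested. S100a8, a subunit of the calcium-binding alarmin calprotectin (chromosome 3, 90472993 to 90473956), went from 6.67 to 2602 FPKM (8.41 ± 0.67), and its partner S100a9 from 7.88 to 2148 (7.92 ± 0.71); the authors' deposited table lists q as 0 for these 3 genes. Krt1, a keratin of cornified epidermis (chromosome 15, 101675857 to 101681217), rose from 2.05 to 66.7 FPKM (4.47 ± 0.54). Cell division genes rose with them, including the ubiquitin-conjugating enzyme Ube2c (3.78 to 22.7 FPKM, 2.31 ± 0.52) and cyclin B1, Ccnb1 (2.26 ± 0.48).

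The cell cycle list had 17 of 32 measured members higher and 0 lower (24 higher adjusted over the list alone, median 1.34, adjusted p = 2.95e-17, Fisher's exact test). The inflammation list had 14 of 23 higher and 0 lower (18 adjusted over the list alone, median 1.92, adjusted p = 1.76e-15, Fisher's exact test). It includes the beta-defensin Defb3 at 22.2 and 759 FPKM and the iron-sequestering protein Lcn2 at 2.97 and 29.5. The neutrophil list had 3 of 7 higher (5 adjusted over the list alone, adjusted p = 0.00688, Fisher's exact test); 2 of those 3, S100a8 and S100a9, are also on the inflammation list and are made by stressed keratinocytes too. The cornified envelope list had 5 of 23 higher (8 adjusted over the list alone, median 0.99, adjusted p = 0.00385, Fisher's exact test). The antioxidant list had 6 of 36 higher (8 adjusted over the list alone, median 0.22, adjusted p = 0.00397, Fisher's exact test), led by the glutathione transferase Gsta1 (24.0 to 175 FPKM, 2.81 ± 0.45) and the aldo-keto reductase Akr1b8 (4.31 to 36.3, 2.81 ± 0.44). Invasion and matrix remodelling had 4 of 20 higher (7 adjusted over the list alone, adjusted p = 0.0168, Fisher's exact test), with stromelysin Mmp3 at 0.805 and 20.3 FPKM (3.56 ± 0.59).

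Salivary genes went both ways: 3 of 15 fell and 3 rose (3 and 3 adjusted over the list alone, median -0.61, adjusted p = 1.87e-04 for lower and 0.0557 for higher, Fisher's exact test), and the lower call ended at a q threshold of 0.01 (adjusted p = 0.172, Fisher's exact test). Dcpp1 fell from 787 to 108 FPKM (-2.85 ± 0.73), while carbonic anhydrase Car6, secreted into saliva, rose from 5.36 to 77.97 (3.64 ± 0.79) and the prolactin-inducible protein Pip from 0.353 to 13.4 (3.41 ± 0.76). Fast muscle and fat markers had low medians with few members past the test. The fast muscle list had a median of -1.13 with 1 of 19 lower (3 adjusted over the list alone), the myosin-binding protein Mybpc2 (93.1 to 19.0 FPKM, -2.23 ± 0.53), and the adipocyte list a median of -1.43 with 0 of 10 past the test (5 lower adjusted over the list alone). The basal keratinocyte list had a median of 1.23 and 2 of 12 higher (7 adjusted over the list alone). Krt13, Krt14, Krt16, Krt6a and Krt6b exceeded the authors' read limit in group 3 and were not tested.

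Across all genes 330 were higher and 37 lower among 13114 tested, and 1580 had an unadjusted p under 0.05. Among genes at 5 FPKM or more in each group the median log2 ratio was -0.10. After centring on it and retesting, 329 were higher and 19 lower, and with 1 variance per gene shared by all groups 343 and 64, both alternatives chosen after seeing the data. The tyrosine kinase ligands Areg (0.405 to 7.70 FPKM) and Hbegf (2.70 to 14.6), and the glucose transporter Slc2a1 (7.78 to 44.6), also rose. The DNA repair list (20 measured) and the p53 target list (21 measured) had 0 genes past the test, with medians of 0.14 and 0.08.

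Group 4 against group 1. The same kinds of gene led in group 4. Sprr2d reached 1076 FPKM (9.09 ± 0.49), S100a8 3184 (8.70 ± 0.52), S100a9 2974 (8.39 ± 0.58) and Krt1 62.2 (4.37 ± 0.32). Salivary secretory genes were far lower: Dcpp1 (chromosome 17, 24017843 to 24019820) went from 787 to 11.9 FPKM (-5.93 ± 0.52) and the proline-rich protein gene Prb1 from 834 to 17.4 (-5.51 ± 0.62). Sbp, a secreted spermine-binding protein that is not on the salivary list, went from 9676 to 105 FPKM (-6.52 ± 0.64). Chia, an acidic chitinase, fell from 265 to 1.20 FPKM (-6.92 ± 0.42).

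Inflammation had 16 of 22 higher (16 adjusted over the list alone, median 1.53, adjusted p = 5.18e-15, Fisher's exact test), and the cell cycle 19 of 31 (24 adjusted over the list alone, median 1.21, adjusted p = 1.19e-15, Fisher's exact test), including Ube2c (2.36 ± 0.35) and Ccnb1 (2.20 ± 0.31). The cornified envelope list had 10 of 23 higher (16 adjusted over the list alone, median 1.21, adjusted p = 1.54e-06, Fisher's exact test) and the basal keratinocyte list 7 of 13 (8 adjusted over the list alone, median 1.17, adjusted p = 2.30e-05, Fisher's exact test). Krt5, a basal keratin, stood at 342 and 1100.3 FPKM but did not pass. Epithelial adhesion had 5 of 14 higher (11 higher and 2 lower adjusted over the list alone, median 1.23, adjusted p = 0.00596, Fisher's exact test), with desmoglein Dsg3 at 5.56 and 37.0 FPKM (2.54 ± 0.32). The antioxidant list had 10 of 36 higher (13 higher and 3 lower adjusted over the list alone, median 0.39, adjusted p = 1.50e-04, Fisher's exact test), led by Akr1b8 (3.10 ± 0.31) and Gsta1 (2.94 ± 0.31). Invasion genes had 5 of 19 higher (10 higher and 2 lower adjusted over the list alone, adjusted p = 0.0220, Fisher's exact test). Immediate early genes had 5 of 18 higher (9 adjusted over the list alone, median 0.70, adjusted p = 0.0181, Fisher's exact test).

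Markers of blood cells moved with group 4. The neutrophil list had 8 of 11 higher and 1 lower (9 and 1 adjusted over the list alone, median 2.97, adjusted p = 1.96e-07, Fisher's exact test), the lower member being lactoferrin, Ltf, which is on the salivary list too, and the erythrocyte list 3 of 6 higher (3 adjusted over the list alone, median 1.59, adjusted p = 0.0240, Fisher's exact test), among them the red cell anion exchanger Slc4a1 at 0.0786 and 3.70 FPKM. Salivary genes had 7 of 14 lower and 1 higher (9 and 2 adjusted over the list alone, median -1.88, adjusted p = 9.17e-06, Fisher's exact test). Adipocyte genes had 4 of 10 lower (7 lower and 1 higher adjusted over the list alone, median -1.54, adjusted p = 0.00583, Fisher's exact test), with carbonic anhydrase Car3 at 96.4 and 19.7 FPKM (-2.23 ± 0.42). Oxidative phosphorylation had 5 of 23 lower (9 adjusted over the list alone, median -0.81, adjusted p = 0.0193, Fisher's exact test), the largest being the muscle-type cytochrome oxidase subunit Cox8b (2557 to 966 FPKM). The fast muscle list had a median of -0.75 with 3 of 19 lower (3 adjusted over the list alone), among them the calcium buffer parvalbumin, Pvalb (755 to 168 FPKM, -2.16 ± 0.41). Xenobiotic P450 genes had 4 of 16 lower and 1 higher (4 and 2 adjusted over the list alone, adjusted p = 0.0299, Fisher's exact test), led by Cyp2a5 (33.6 to 4.76 FPKM, -2.59 ± 0.35); their median of -0.08 turned to 0.08 after centring. At a q threshold of 0.01 the calls ended for oxidative phosphorylation (adjusted p = 0.0690), xenobiotic P450 (0.249), immediate early (0.866), adipocyte (0.971) and erythrocyte genes (0.172), all by Fisher's exact test.

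Among 13111 genes tested, 655 were higher and 512 lower, and 3219 had an unadjusted p under 0.05. The median log2 ratio of genes at 5 FPKM or more was -0.16, and after each difference was centred on that median and retested 790 were higher and 244 lower, 76.4% higher against 56.1%. Alcohol and aldehyde metabolism went both ways, with 3 of 19 higher and 2 lower (3 and 2 adjusted over the list alone): the alcohol dehydrogenase of stratified epithelium Adh7 went from 72.6 to 305 FPKM and the liver-type Adh1 from 64.7 to 20.3. The p53 target list had 2 of 21 higher, Plk2 and Gtse1, and 1 lower, Ccng1 (4 and 1 adjusted over the list alone), and DNA repair 0 of 19. With 1 variance per gene shared by all groups, chosen after seeing the data, 396 genes passed in place of 1167.

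Group 3 against group 2. The 8 largest rises were again the alarmins S100a8 and S100a9 and genes of the Sprr2 family. S100a8 stood at 13.0 FPKM in group 2 and 2602 in group 3 (7.54 ± 0.69), Sprr2d at 2.96 and 815 (7.69 ± 0.63), and Krt1 stood at 1.99 and 66.7 FPKM. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose from 1.03 to 17.1 FPKM (3.16 ± 0.43) and Mmp3 from 1.15 to 20.3 (3.31 ± 0.60). The 8 largest falls were Fibin, C1qtnf3, Fbln7, the imprinted RNA H19, the corneal-type proteoglycan keratocan, Kera (5.10 to 0.391 FPKM, -2.13 ± 0.36), the microfibril protein Mfap4 (59.5 to 14.6, -1.95 ± 0.48), Mybpc2 (79.6 to 19.0, -2.01 ± 0.55) and cardiac-type actin Actc1 (316 to 84.9, -1.88 ± 0.56). In the authors' deposited table Kera had q = 0.0229 and Mfap4 q = 0.0046.

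Inflammation had 15 of 23 higher (18 adjusted over the list alone, median 1.89, adjusted p = 8.36e-20, Fisher's exact test), and the cell cycle 8 of 32 (19 adjusted over the list alone, median 1.07, adjusted p = 8.35e-07, Fisher's exact test), among them the mitotic survivin gene Birc5 (2.78 to 12.5 FPKM, 1.84 ± 0.59). The neutrophil list had 3 of 7 higher (5 adjusted over the list alone, adjusted p = 0.00240), the antioxidant list 5 of 36 (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.00397) and invasion 4 of 20 (6 and 3, adjusted p = 0.00397), each by Fisher's exact test. The cornified envelope list had 4 of 23 higher (4 adjusted over the list alone, median 0.94, adjusted p = 0.00623, Fisher's exact test) and the basal keratinocyte list 3 of 12 (5 adjusted over the list alone, median 1.10, adjusted p = 0.0101, Fisher's exact test), with P-cadherin, Cdh3, at 2.16 and 10.9 FPKM (1.91 ± 0.57). The salivary list had 3 of 17 higher and 0 lower (3 and 1 adjusted over the list alone, adjusted p = 0.0250, Fisher's exact test), among them Car6 (2.53 to 77.97 FPKM, 4.48 ± 0.81) and Pip, while its median was -0.04 and turned positive after centring. Immediate early genes had 2 of 18 lower (2 adjusted over the list alone, adjusted p = 0.00963, Fisher's exact test), Ctgf and the nuclear receptor Nr4a1, although their median was 0.25. The interferon list had a median of -0.53 with 0 of 23 past the test (2 lower adjusted over the list alone). At a q threshold of 0.01 the calls for the cell cycle, basal keratinocyte and immediate early lists ended, each with an adjusted p of 1 by Fisher's exact test.

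Among 13127 genes tested, 211 were higher and 30 lower, and 1351 had an unadjusted p under 0.05. After centring and retesting 185 were higher and 20 lower, and with 1 variance per gene shared by all groups 242 and 83, both chosen after seeing the data. The fast muscle list had a median of -1.05 with 1 of 19 lower (1 adjusted over the list alone).

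Group 4 against group 2. Group 4 was lower than group 2 in interferon-stimulated and salivary genes and higher in alarmin, cornified envelope and antioxidant genes. Isg15 stood at 49.99 FPKM in group 2 and 6.94 in group 4 (-2.68 ± 0.44), and the interferon-inducible Ifi27l2a at 245 and 47.1 (-2.36 ± 0.38). Chia fell from 210.03 to 1.20 FPKM (-6.59 ± 0.45) and Dcpp1 from 359.9 to 11.9 (-4.80 ± 0.54). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (chromosome 9, 77602342 to 77642296), rose from 7.94 to 76.9 FPKM (3.12 ± 0.35), Slc7a11 from 1.03 to 20.7 (3.42 ± 0.30) and S100a8 from 13.0 to 3184 (7.83 ± 0.54).

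The interferon list had 10 of 23 lower and 0 higher (15 lower adjusted over the list alone, median -0.96, adjusted p = 1.16e-09, Fisher's exact test). The antioxidant list had 11 of 36 higher (15 higher and 3 lower adjusted over the list alone, median 0.49, adjusted p = 4.41e-07, Fisher's exact test). Inflammation had 15 of 22 higher (18 adjusted over the list alone, median 1.45, adjusted p = 8.58e-16, Fisher's exact test), the cell cycle 15 of 31 (19 adjusted over the list alone, median 0.93, adjusted p = 5.75e-13, Fisher's exact test), the cornified envelope 9 of 22 (14 adjusted over the list alone, median 1.03, adjusted p = 4.71e-07, Fisher's exact test) and the basal keratinocyte list 5 of 13 (7 adjusted over the list alone, median 1.00, adjusted p = 7.81e-04, Fisher's exact test). Invasion had 5 of 20 higher and 1 lower (8 and 4 adjusted over the list alone, adjusted p = 0.00583, Fisher's exact test). Fibroblast and collagen genes had 6 of 16 lower (9 adjusted over the list alone, median -0.78, adjusted p = 1.97e-05, Fisher's exact test). The neutrophil list had 9 of 11 higher (10 higher and 1 lower adjusted over the list alone, median 2.95, adjusted p = 1.28e-10, Fisher's exact test), the erythrocyte list 3 of 6 (3 adjusted over the list alone, adjusted p = 0.00872, Fisher's exact test), and the salivary list 7 of 16 lower with 2 higher (10 and 2 adjusted over the list alone, median -1.70, adjusted p = 7.79e-07, Fisher's exact test). The adipocyte list had a median of -1.30 with 2 of 10 lower (8 adjusted over the list alone), and the fast muscle list a median of -0.76 with 2 of 19 lower (3 adjusted over the list alone).

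Among 13124 genes tested, 434 were higher and 295 lower, and 2481 had an unadjusted p under 0.05. The median log2 ratio of genes at 5 FPKM or more was -0.14, and after centring and retesting 471 were higher and 156 lower, 75.1% higher against 59.5%. Adh7 was higher in group 4, at 71.0 and 305 FPKM (2.09 ± 0.43), as were Areg (2.18 ± 0.40) and Hbegf (1.90 ± 0.34). With 1 variance per gene shared by all groups, chosen after seeing the data, 280 genes passed in place of 729.

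Group 4 against group 3. Granule genes of immature granulocytes and genes of red cell precursors were higher in group 4. The cathelicidin Camp (chromosome 9, 109749891 to 109751970) stood at 0.266 FPKM in group 3 and 47.6 in group 4, the neutrophilic granule protein Ngp (chromosome 9, 110322312 to 110325516) at 0.0973 and 37.2, neutrophil elastase Elane at 0.0117 and 6.84, and the red cell anion exchanger Slc4a1 at 0.0389 and 3.70. The authors' deposited table gave q = 1.51e-10 for Camp and q = 0.00493 for Elane. The seminal vesicle genes Svs4 (chromosome 2, 164101692 to 164104043) and Svs5 rose from 0.0796 to 28.0 FPKM (4.75 ± 0.48) and from 0.102 to 26.7 (4.65 ± 0.48). Salivary secretory genes were lower, with Car6 at 77.97 and 2.72 FPKM (-4.41 ± 0.89) and Dcpp1 at 108 and 11.9 (-3.08 ± 0.87). Chia, which is not on the salivary list, stood at 54.6 and 1.20 FPKM (-4.66 ± 0.84).

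The neutrophil list had 5 of 12 higher and 0 lower (6 adjusted over the list alone, median 0.88, adjusted p = 3.52e-10, Fisher's exact test), and the erythrocyte list 2 of 6 higher (3 adjusted over the list alone, median 1.90, adjusted p = 7.81e-04, Fisher's exact test). The salivary list had 4 of 16 lower and 0 higher (5 adjusted over the list alone, median -2.41, adjusted p = 1.11e-07, Fisher's exact test). Fibrinogen Fgb was higher (0.0489 and 1.92 FPKM); it was the only measured member of the liver acute phase list, so its list is not read as a group. The interferon list had a median of -0.45 with 1 of 22 lower (1 adjusted over the list alone), the chemokine Cxcl9 at 7.61 and 1.18 FPKM (-1.98 ± 0.49). Cell cycle, cornified envelope and basal keratinocyte members had 0 past the test, and for basal keratinocytes the median of 12 was -0.07.

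Among 12918 genes tested, 22 were higher and 16 lower, and 105 had an unadjusted p under 0.05. That share is again below 0.05, so the authors' p-values and the SEs may be too large in this pair. Few calls therefore need not mean few differences. Without the salivary, seminal vesicle and blood precursor genes 19 remained past the threshold, 7 higher and 12 lower, and after centring and retesting 18 passed, 5 higher and 13 lower, 27.8% higher against 57.9%. With 1 variance per gene shared by all groups 9 were higher and 27 lower; these 3 alternatives were chosen after seeing the data. With the standard errors of these groups, 42% of simulated log2 changes of 2 were recovered in this pair, against 82% in group 4 against group 1. Only 200 of 13074 genes were changed in the simulation, which took the SEs as the real spread. The deposited q was adjusted over all 6 comparisons with more calls, which loosens the p cut, so these shares may understate detection in the data. Smaller differences could still be missed more often in this pair.

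**Figure D2:**
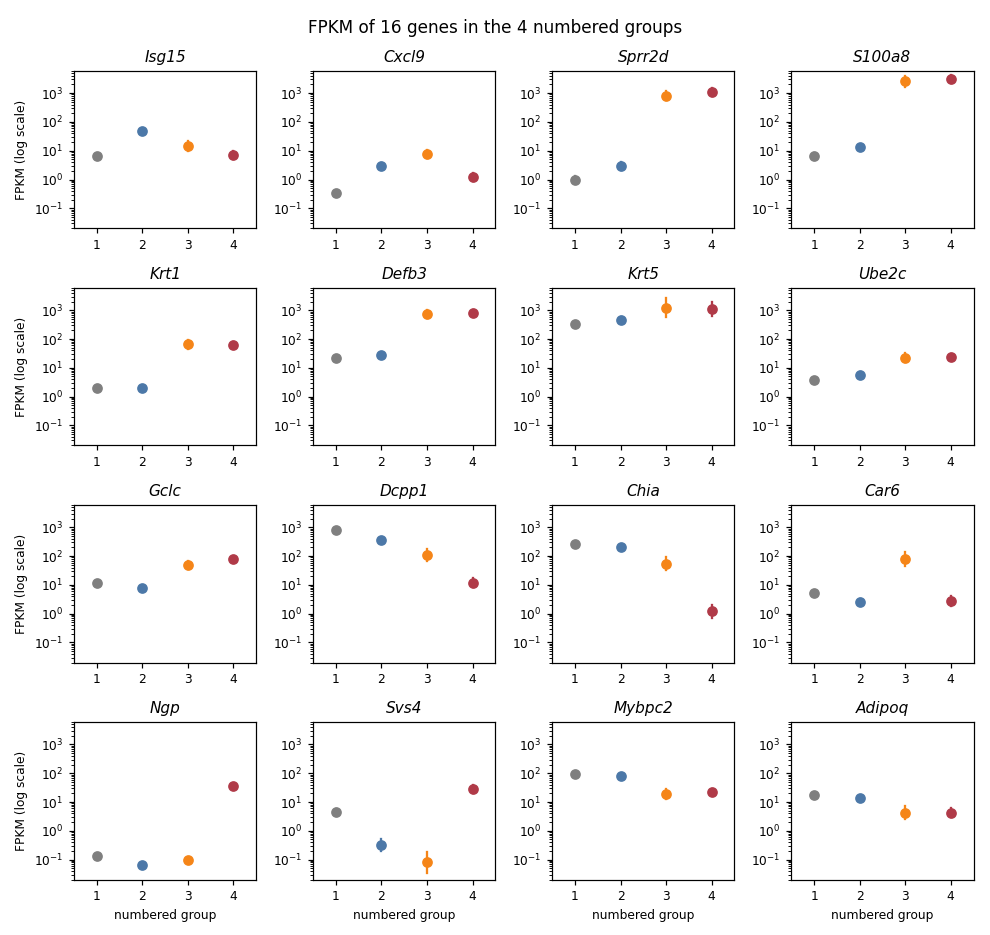
FPKM of 16 genes (1 panel each, log vertical axis) in groups 1 to 4 (horizontal axis); points are the authors' value for a group and lines are 1 SE to either side, not given for Ngp. S100a8 stands at 6.67, 13.0, 2602 and 3184 FPKM, and Isg15 at 6.502, 49.99, 14.7 and 6.94.

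Setting pairs of groups against pairs. For each of the 3 ways to set 2 groups against the other 2, the difference of the group log2 levels was tested for 13044 genes with the variances implied by the authors' statistics. One of these 3 contrasts is the interaction of ethanol with 4-NQO and the others are the main effects, but which is which is not given in the sources used here. Each contrast compares the sum of the log2 levels of 2 groups with that of the other 2, so a single group can go the other way. Groups 3 and 4 against groups 1 and 2 gave 1934 genes, with 3544 at an unadjusted p under 0.05. The sum for groups 3 and 4 was higher for 898 of them and lower for 1036. Groups 1 and 4 against groups 2 and 3 gave 12 genes (89 unadjusted). Svs4 and Svs5 were higher in groups 1 and 4. For 10 genes the sum for groups 1 and 4 was lower, including the interferon-inducible Cxcl9, Isg15, Oas1a, Oasl2 and Apol9b. Chia is also among the 10, although it stood highest in group 1, at 265, 210, 54.6 and 1.20 FPKM in groups 1 to 4. Groups 1 and 3 against groups 2 and 4 gave 14 (141 unadjusted). The 89 and 141 of 13044 genes are shares below 0.05 too, so the variances may be too large and differences missed. The sum for groups 1 and 3 was higher for 12, including Amy2b, Car6, Chia, Dcpp1, Dcpp2 and Dcpp3. It was lower for 2, the chitinase-like Chi3l3 and the endothelial gene Apold1. Chia, Dcpp1, Dcpp2 and Dcpp3 stood lower in group 3 than in group 2, with Dcpp1 at 787, 360, 108 and 11.9 FPKM in groups 1 to 4.

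Shared calls between comparisons. Group 3 against group 1 and group 4 against group 2 have no group in common, and 261 genes were higher in both, where 9.86 would be shared if the calls were independent, and 26 were lower in both, where 0.752 would be. Across 12036 genes the log2 differences of these comparisons had Pearson's r = 0.91 and Spearman's rho = 0.92; genes are not independent replicates, and the simulated covariance with unchanged groups was near 0 against 0.350 in the data. Group 3 against group 2 and group 4 against group 1, again with no common group, shared 184 higher genes (9.85 for independent calls) and 18 lower ones (1.12), with r = 0.84. Group 2 against group 1 and group 4 against group 3 shared 0 higher genes and 9 lower ones (0.0352), with a weaker r = 0.28 and rho = 0.27. In opposite directions, Svs4 and Svs5 were lower in the former and higher in the latter, 2 genes where 0.00754 would be for independent calls (p = 1.83e-05, Fisher's exact test), and Cxcl9 was higher and then lower, 1 gene where 0.0840 would be. Comparisons with a common group shared 300 higher and 33 lower genes (group 3 and group 4, each against group 1), where 15.2 and 1.46 would be for independent calls. Unchanged groups in the simulation shared 0, which says little because they give almost no calls. Pearson's r of these differences was 0.93, against 0.11 simulated for unchanged groups with a common group.

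**Figure D3:**
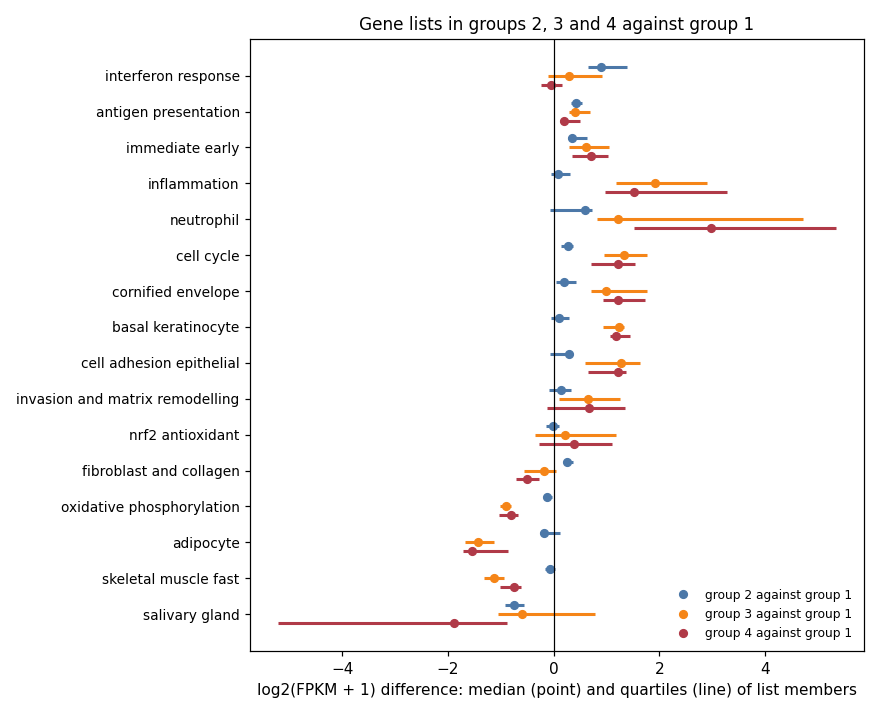
Median log2 difference of the measured members of 16 gene lists (vertical axis) for groups 2, 3 and 4, each against group 1 (horizontal axis, log2 of FPKM + 1); points are medians and lines run between the quartiles. The interferon list has medians of 0.89, 0.29 and -0.06 (0.10 after centring), and the cell cycle list 1.34 in group 3 and 1.21 in group 4.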

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

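The tests of explanations here, and the use of all 3 ways of pairing the groups in place of 1 planned interaction, were chosen only after the results were seen. Each contrast is listed because the test of the difference between comparisons that share no group was passed by some genes: 1934 genes for groups 3 and 4 against groups 1 and 2, 12 genes for groups 1 and 4 against groups 2 and 3, and 14 genes for groups 1 and 3 against groups 2 and 4. Besides Svs4 and Svs5 the 12 were Cxcl9, Apol9b, Apol9a, Chia, Gm4841, Isg15, Oas1g, Chi3l4, Oasl2 and Oas1a, and the 14 included Car6, Chia, Dcpp1, Dcpp2 and Dcpp3. Each contrast tests a main effect or the interaction, but which is unknown, because the group numbers are not linked to treatments. None of these genes can be assigned to a treatment.

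Against group 1 the basal keratinocyte list had medians of 1.23 in group 3 and 1.17 in group 4, and the fast muscle list -1.13 and -0.75, though of these only the basal list in group 4 passed its test (adjusted p = 2.30e-05, Fisher's exact test). A lower share of muscle cells alone would raise the markers of every other cell type alike. The basal keratinocyte median in group 4 against group 1 lay 1.16 above the highest of the endothelial, fibroblast and macrophage medians (interquartile range of the basal list 0.38). This argues against a loss of muscle cells alone. It cannot decide on a lower share of muscle tissue together with the connective tissue and vessels within it, which need not raise those 3 lists. The cell cycle median lay 0.0389 above that of the basal keratinocyte list. This cannot decide whether a larger share of epithelium accounts for the rise of the cell cycle list. The added 1 FPKM shrinks the differences of genes near 1 FPKM in group 1, where many cell cycle genes stood. Ccnb1, at 1.25 FPKM in group 1, had a deposited log2 ratio of 2.90, against 2.20 on the log2(FPKM + 1) scale. For some inflammation genes a larger share of epithelium does not suffice. Of 19 genes, 9 exceeded the upper quartile of the basal list, 1.44, by more than the 2-sided normal bound of their SE. Here single genes were counted, whereas for the cell cycle list the medians were compared. The p of 2.81e-10 (exact binomial test) takes the genes as independent and each as standing at that quartile, so it does not measure how far a larger share falls short. What else raised the inflammation genes stays open. The rise cannot be assigned to a treatment, because the group numbers are not linked to treatments. More neutrophils are untested as a source. The mature neutrophil list had log2(FPKM + 1) medians of 0.71 in group 3 and 0.69 in group 4 against group 1. In these comparisons 2 and 5 of 13 genes were past the test. On the log2(FPKM + 0.01) scale, which shrinks differences at low levels less, the medians were 2.48 and 2.55. On that scale 10 of 13 genes were more than 2-fold higher in group 3 than in group 1, and 10 in group 4.

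The seminal vesicle genes Svs4 and Svs5 stood at 4.46 and 6.04 FPKM in group 1, at 0.328 and 0.475 in group 2, at 0.0796 and 0.102 in group 3 and at 28.0 and 26.7 in group 4. Male mice among the samples are argued against by the Y-linked genes, whose highest level in groups 1 and 4 was 0.00193 FPKM. A single outside source of RNA in both groups and separate sources of the same tissue cannot be told apart: the FPKM ratios of group 4 to group 1 for 9 seminal vesicle genes did not differ beyond their SE (heterogeneity p = 0.977 by a chi-squared test, not an exact one), which either would give. The Y-linked genes argue against seminal vesicle of the sampled mice too, and whether the RNA came from tissue of other animals or was carried between libraries stays open.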

How the results depend on the processing

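The retest after centring, the single variance per gene and the leaving out of salivary, seminal vesicle and precursor genes were chosen only after the results were seen. In the order group 2, 3 and 4 against group 1, group 3 and 4 against group 2, and group 4 against group 3, the counts were 115, 367, 1167, 241, 729 and 38. At a q threshold of 0.01 they fell to 65, 217, 653, 144 and 369 in the first 5, and the contrast of groups 1 and 2 with groups 3 and 4 fell from 1934 to 1052. With Bonferroni they were 31, 87, 241, 68, 145 and 11. A fold change of at least 2 left 70 genes in group 2 against group 1. A floor of 5 FPKM left 243 in group 3 against group 1 and 24 in group 4 against group 3. These alternatives are stricter by construction. Adjustment within each comparison and over the genes past the filter alone, 2 changes together, moved counts both ways, to 72, 350, 1708, 205, 938 and 27. The lower genes of group 4 against group 1 went from 512 to 842. A pooled adjustment sets 1 p cut for all comparisons. Within a comparison the cut is looser where small p-values are many (3219 under 0.05 in group 4 against group 1) and stricter where they are few (105 in group 4 against group 3). The 2 changes were not tested apart. A single variance per gene, the mean of its 4 group variances, gave 19 in group 2 against group 1, 396 in group 4 against group 1 and 280 in group 4 against group 2. It gave 407 in group 3 against group 1, 325 in group 3 against group 2 and 36 in group 4 against group 3. Group 3 had the largest typical SE, 0.492, and the mean brings its variance into the pairs without it. No other cause was tested. In group 4 against group 3 the retest after centring gave 18, where the cause was not tested, and leaving out the salivary, seminal vesicle and precursor genes gave 19, since those genes were removed. Genes higher in both group 3 against group 1 and group 4 against group 2 numbered 156 at q under 0.01 and 173 at 5 FPKM, and lower ones 6 at q under 0.01. For group 3 against group 2 with group 4 against group 1 these were 116 higher and 3 lower at q under 0.01, and for group 2 against group 1 with group 4 against group 3, 4 lower. The named genes kept their direction with pseudocounts of 0 and 0.1, which cannot change a sign. They kept it after centring too, where the shift was small beside their differences, so neither check says much. After centring 14 list medians changed sign, among them xenobiotic P450 in group 4 against group 1 and salivary gland in group 3 against group 2. The majority in group 4 against group 3, 22 higher and 16 lower, turned to 9 and 15 at 5 FPKM, 5 and 13 after centring and retesting, 9 and 27 with a single variance, and 7 and 12 without the salivary, seminal vesicle and precursor genes. Of the 50 list calls, 10 ended at q under 0.01. No paired analysis was possible because the tables hold 1 value per group and none per sample. For the same reason leaving out replicates, limma, permutation and other splits of the samples could not be run, and the read depth that limits small differences is unknown.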

Other observations

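The marker lists of blood precursors and of other tissues, and the tests on them, were chosen only after the results were seen. Some planned lists have not been described above. Growth factor ligands and receptors had 3 of 19 members higher in group 3 than in group 1 (3 adjusted over the list alone; adjusted p = 0.103, Fisher's exact test): Areg, Hbegf and Tgfa, ligands of the EGF receptor, with Tgfa at 2.54 and 7.90 FPKM (1.33 ± 0.45). In group 4 the same 3 genes were higher than in group 1 (3 of 18; 6 adjusted over the list alone; adjusted p = 0.351, Fisher's exact test). Among chromatin modifiers, Uhrf1, which guides maintenance DNA methylation, and the helicase Hells were the 2 of 24 members higher in group 3 than in group 1 (1.47 ± 0.52 and 1.18 ± 0.44; 2 adjusted over the list alone; adjusted p = 0.619, Fisher's exact test). In the retinoid list 2 of 17 were higher in group 3, the retinoic acid hydroxylase Cyp26b1 (1.46 ± 0.40) and Lrat, which esterifies retinol (2 adjusted over the list alone, adjusted p = 0.388, Fisher's exact test). Notch, Wnt and hedgehog genes had 3 of 17 higher in group 4 than in group 1, namely Notch1, its ligand Jag1 and Wnt10a (6 adjusted over the list alone; adjusted p = 0.311, Fisher's exact test). None of these lists passed its test in those comparisons.

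The folds of the added lists are ratios of FPKM + 0.01, not of FPKM + 1, and many members stood under 1 FPKM. Between groups 4 and 3, the added granulocyte precursor list had 12 of 13 genes more than 2-fold higher, 7 past the test, with Camp at 47.6 and Ngp at 37.2 FPKM in group 4. The erythroid precursor list had 12 of 12 more than 2-fold higher and 4 past the test, with Alas2, the first enzyme of heme synthesis in red cells, at 4.11 and 17.1 FPKM. The seminal vesicle list had 9 of 9 more than 2-fold higher and 4 past the test. The mature neutrophil list had 3 of 13 more than 2-fold higher and 2 past the test, the B-lineage marrow list 3 of 10 and 0, the bone cell list 3 of 11 and 1, and the exocrine pancreas list 3 of 26 and 0.

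More mature neutrophils in the tissue are argued against as the source of the granulocyte precursor genes in group 4: the precursor median exceeded that of the mature list by 5.85 on the log2(FPKM + 0.01) scale against group 3, with an interquartile range of 1.54 in the mature list, and by 2.06 on the log2(FPKM + 1) scale, with a range of 0.78. Blood or marrow cells carrying precursors of both lineages are a candidate source, since 100% of the 8 erythroid genes that had not passed the test were more than 2-fold higher in plain FPKM in group 4 than in each other group. Of these 8, 6 stood under 1 FPKM in group 4, and all 8 had an unadjusted p under 0.05 against group 3 in the authors' deposited table. Marrow, spleen or circulating cells were not separated, and whether 1 or more of the samples in group 4 carry the signal was not tested, as values per sample were not used here. The difference in these genes cannot be assigned to a treatment, because the group numbers are not linked to treatments.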
